A study of Mus musculus with 24 samples.

How the data were processed

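Affymetrix arrays measured gene expression in whole hearts of FVB/N mice that were nontransgenic (Ntg), carried a dominant negative PI3K transgene (dnPI3K, lower PI3K activity per the labels) or carried a constitutively active PI3K transgene (caPI3K, higher activity per the labels). Mice had a sham operation or a myocardial infarction (MI) at 4 months of age, and hearts were taken 8 weeks later. The 24 arrays make 6 groups of 4. On the caPI3K MI samples the name of a tag reads caPI3K-sham while its text, the titles and the descriptions give MI, and they were taken as MI. The labels say that each heart was homogenized on its own but do not state that each array holds a separate animal, so p-values measure the spread between these arrays. Sex of the animals is not given in the sources used here.

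The deposited values are signal intensities that the submitters' processing notes attribute to MAS5. The version and the scaling target are not given in the sources used here. All 24 arrays have a mean signal of 500 after trimming 2 percent at each end, from 500.003 to 500.004, so they were scaled to a shared level before deposit and no further normalization was applied. The bright end still differs, with the 99th percentile of signal at 16086 to 20892 over the arrays. Small changes of bright genes may come in part from this. Of the 45101 probe sets, 64 are controls and were left out, 34945 name 1 gene, 932 name several genes and 9160 are absent from the annotation used. Gene IDs of 34741 probe sets were found in the RefSeq list for mouse assembly GRCm38.p6, and 0 symbols differed. A probe set was kept when its signal was above the 40th percentile of its own array on at least 4 arrays, whatever their group, which kept 33061. Each gene was represented by the probe set with the highest mean over all arrays, which left 14763 genes. Of these 6946 had at least 2 probe sets to choose from. Signals were transformed as log2 of signal plus a pseudocount of 11.2, the median signal divided by 10, so changes of dim genes are compressed. Probe sets without 1 gene were tested apart, and calls among these 5934 numbered 13, 181 and 9 for MI in Ntg, dnPI3K and caPI3K hearts. They are not named here.

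A linear model with a mean for each of the 6 groups was fitted in limma 3.58.1 under R 4.3.3, with an intensity trend in the empirical Bayes step and 18 residual degrees of freedom. Files were read with the package data.table, version 1.17.8. The 8 comparisons are MI against sham in each genotype, the 3 differences between these MI effects, and each transgenic sham group against Ntg sham. P-values were adjusted over the tested genes by the Benjamini-Hochberg method, and a gene is called changed at an adjusted p below 0.05. A value after a change is its standard error (SE) from the model; a value after a group mean is the standard deviation (SD) of 4 arrays unless another n is given. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

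Gene groups were 37 lists of symbols written down from general knowledge of heart biology: metabolism, matrix, contraction, signalling, stress responses and markers of cell types that a heart sample may hold. Some lists share genes, so their shifts are not separate results. *Col1a1*, *Col1a2*, *Col3a1*, *Dcn*, *Lum* and *Mfap4* are in both the matrix and the fibroblast lists. *Nppa*, *Myl4* and *Myl7* are in both the fetal and wall-stress and the atrial lists. The 35 lists with at least 5 measured genes were tested with camera, with a preset correlation of 0.01 between genes, adjusted over lists; the remaining lists are described only. The same test was repeated with a correlation estimated from the residuals. Which setting is nearer the truth was not tested. At the preset correlation, regroupings of the arrays called as many lists as the real groups, as given below. Members were also adjusted over their list alone.

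The genes named in each comparison come first from a set written down in advance, of which 15 were measured (Cpt1b was not named on the array). Next are the 10 called genes with the largest change in each direction and no overlap between the arrays of the groups. Last are up to 4 members of smallest p in each called list, called or not. Not all of these are printed here, but the tallies of named genes under alternatives were drawn from all of them. Where a difference of MI effects called no gene, the 5 genes of smallest p are given as values. Genes chosen after values were seen are said to be so. The number of arrays, not a depth of reading, limits precision.

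The code was tested on simulated data with 14763 genes, of which 200 were changed, in 5 runs. For MI in Ntg hearts it recovered 25.6%, 60.7% and 86.5% of genes changed by 0.5, 1 and 2 log2 units, with 4.4, 4.8 and 9.8 false calls on average, and 100% of recovered genes had the right direction. For a difference of MI effects between dnPI3K and Ntg the shares were 6.5%, 44.9% and 74.9%, and between caPI3K and Ntg 5.8%, 46.2% and 75.3%. A comparison left unchanged gave 0 calls over 15 runs. The list test called 1 list over 10 runs without change, and called a list shifted by 0.3 in 10 of 10 runs. The simulated genes varied independently of each other. These runs thus do not show how often the list test makes false calls when genes are correlated, as in real arrays.

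Alternatives comprised quantile normalization, a pseudocount of 1.12 or 56.0, a filter at the 60th percentile or none, every probe set in place of 1 per gene, a fit on the compared groups only, a term for array numbers under 1000, and leaving out each array in turn, the sham arrays numbered 415 to 418, or the 3 caPI3K sham arrays that carry Y-linked signal. Comparisons, filter, threshold, lists and most alternatives were set before the data were examined; the comparison of caPI3K with dnPI3K over both operations, the sex-based and array-number exclusions and the scores of single arrays were added afterwards. Array image files were not analysed here. Columns of per-sample values left unused numbered 0.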

Results

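Gene expression in mouse hearts was measured on 24 arrays, 4 in each of 6 groups: Ntg, dnPI3K and caPI3K mice, each 8 weeks after a sham operation or MI. Median signal lay between 103 and 119 on all arrays except dnPI3K MI replicate 1, at 151, and array pairs correlated at 0.911 to 0.964 over the 14763 tested genes.

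*Pik3ca*, which encodes the catalytic subunit p110 alpha, ranged from 10.01 to 10.93 on a log2 scale over the arrays, with means of 10.57 (SD 0.37) in Ntg sham, 10.62 (SD 0.29) in dnPI3K sham and 10.60 (SD 0.07) in caPI3K sham hearts (n = 4 each). After MI the means were 10.69 (SD 0.23), 10.40 (SD 0.21) and 10.55 (SD 0.09). *Pik3r1*, the p85 alpha regulatory subunit, ranged from 10.11 to 11.28. Its sham means were 10.95 (SD 0.38), 10.89 (SD 0.20) and 10.87 (SD 0.21), and its MI means 10.70 (SD 0.27), 10.41 (SD 0.20) and 10.68 (SD 0.21) in the same order. Neither gene was called in any comparison, the smallest adjusted p being 0.0553 for *Pik3r1* after MI in dnPI3K hearts (limma, Benjamini-Hochberg). These probe sets were chosen for the mouse's own transcripts, and whether they read the transgenes is not given in the sources used here, so the values check neither the transgene nor the genotype labels.

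Infarction in Ntg hearts raised genes of the extracellular matrix. *Mfap4*, a microfibril-associated glycoprotein, rose by 4.12 log2 units (SE 0.71, n = 4 arrays per group), from a sham mean of 5.90 (SD 2.21) to 10.02 (SD 0.24). Its signal is at background on Ntg sham replicates 1 to 3 (log2 4.51 to 4.95) and at 9.20 on replicate 4, without which the change is 5.22, so the pseudocount limits the size and no fold is given. *Comp* rose by 1.75 (SE 0.22), *Postn*, a matrix protein of activated fibroblasts, by 1.77 (SE 0.31), *Sfrp2*, a secreted Wnt modulator, by 2.05 (SE 0.36), and *Nox4*, an NADPH oxidase, by 1.74 (SE 0.33). *Nppa*, the atrial natriuretic peptide, rose by 1.28 (SE 0.27), while *Nppb* (0.32, adjusted p = 0.226), *Myh7* (0.51, adjusted p = 0.609) and *Acta1* (0.50, adjusted p = 0.194) did not pass. Without Ntg sham replicate 4, *Acta1* passes (0.79, adjusted p = 4.16e-05) and *Myh7* is at 0.90 (adjusted p = 0.103). *Dio2*, which activates thyroid hormone, rose by 1.75 (SE 0.32), and *Ech1*, an enzyme of fatty acid oxidation, decreased by 0.49 (SE 0.11).

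In all, limma with Benjamini-Hochberg adjustment called 115 genes after MI in Ntg hearts, 101 up and 14 down. Further large increases were those of *Scg2* (2.61, SE 0.57), *Krt18* (1.72, SE 0.29) and *Ccn5* (1.72, SE 0.28), together with *Mlana* (2.84) and *Ccdc136*, which are dim on sham arrays. Among genes that fell, *Slc46a3* decreased by 0.75 (SE 0.14), *H2ac19* by 0.64, *Atcayos* by 0.63, *Magix* by 0.53, *Aldh9a1* by 0.50 (SE 0.12), *Ggct* by 0.47 and *H2az2* by 0.32. At low signal, *Ap4m1* and *4930448K20Rik* fell, the latter by 1.88. *Col3a1* rose by 1.11 (SE 0.25) and *Timp1*, an inhibitor of matrix metalloproteinases, by 1.16 (SE 0.29), but *Col1a1* (1.25, SE 0.34, adjusted p = 0.0891) did not pass. *Myh6* (-0.21), *Atp2a2* (-0.25), *Pln* (-0.25), *Ppargc1a* (-0.38) and *Acadm* (-0.33) did not pass either, with adjusted p from 0.0805 to 0.442. Without Ntg sham replicate 4, *Col1a1* (1.69, adjusted p = 0.000783) and *Acadm* (-0.41, adjusted p = 0.00485) pass. The count depends on single arrays: it was 35, 25, 32 and 674 without Ntg sham replicates 1 to 4 and 44, 40, 56 and 75 without Ntg MI replicates 1 to 4. It was 10 in a fit on these groups alone and 9 without the sham arrays numbered 415 to 418, which leaves Ntg sham replicates 3 and 4, and other groupings of these 8 arrays call up to 356.

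Of 57 measured matrix genes, 27 rose after MI in Ntg hearts and 0 fell (median 0.767; 40 rose when adjusted over the list alone), among them *Fmod* (1.28, SE 0.15) and *Mfap5* (1.16). This list passed camera at adjusted p = 1.86e-44 and at 0.042 with an estimated correlation. Fibroblast markers, some of which are also in the matrix list, moved up too (6 of 20 rose, 11 over the list alone, median 0.385). Examples outside the matrix list are *Pi16* (1.33) and *Islr* (0.80). Their adjusted p was 7.22e-15, and 0.0661 with an estimated correlation. The list of fetal and wall-stress genes shifted up (2 of 16 rose, *Nppa* and *Ccn2*, the latter by 0.87, SE 0.13, at adjusted p = 1.46e-07, and 0.0909 with an estimated correlation). Atrial markers shifted up too (2 of 13 rose, *Nppa* and *Sln*, the latter by 2.18, SE 0.52, at adjusted p = 5.24e-05, and 0.081 with an estimated correlation). Macrophage markers (0 of 26 rose, median 0.243), cell division genes (median 0.271), chemokines, cytokines and complement (median 0.301) and interferon response genes (median 0.267) shifted up as sets, at adjusted p of 0.00421, 0.0237, 0.0176 and 0.00141. None of these held with an estimated correlation (0.536, 0.498, 0.498 and 0.498). They lean on Ntg MI replicate 1, whose list medians relative to the mean over arrays were 0.578, 0.570, 0.306 and 0.726. On the other Ntg MI arrays they were -0.152 to -0.019, -0.236 to 0.104, -0.149 to 0.105 and -0.199 to -0.034.

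Metabolic genes moved down after MI in Ntg hearts by small amounts. Of 28 genes of fatty acid oxidation, 2 fell (*Decr1* and *Ech1*, each at -0.49) and 22 fell over the list alone (median -0.296, adjusted p = 6.24e-20, and 0.0909 with an estimated correlation). Of 74 genes of oxidative phosphorylation 0 passed over all genes and 58 fell over the list alone (median -0.225, adjusted p = 6.77e-34, and 0.157 with an estimated correlation). That median was -0.043 after quantile normalization and -0.069 without the sham arrays numbered 415 to 418. The citric acid cycle (median -0.226, 13 of 19 down over the list alone), PPAR and PGC-1 regulated metabolism (median -0.195, 5 of 20), calcium handling and ion channels (median -0.094, 6 of 32) and sarcomere genes (median -0.206, 10 of 24) shifted down at adjusted p of 2.27e-11, 0.00141, 0.022 and 3.22e-10. These were 0.149, 0.41, 0.498 and 0.317 with an estimated correlation. Quantile normalization ended the call of the sarcomere list (median -0.014, adjusted p = 0.671) and of the calcium list (median -0.073, adjusted p = 0.133). Relative to the mean over arrays, Ntg sham replicates 1 and 2 (415 and 416) were above replicates 3 and 4 for fatty acid oxidation (0.359 and 0.351 against 0.187 and 0.069). So they were for the citric acid cycle (0.311 and 0.242 against 0.116 and -0.014) and sarcomere genes (0.310 and 0.225 against -0.071 and 0.102). Part of these falls may thus rest on replicates 1 and 2. The PPAR and calcium lists did not separate the arrays in this way.

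In dnPI3K hearts infarction raised the same kinds of matrix genes and lowered genes of mitochondrial metabolism. *Mfap4* rose by 4.59 (SE 0.71; 5.45 without dnPI3K sham replicate 3, the sham array furthest above background), *Comp* by 2.29 (SE 0.22), *Lox*, which crosslinks collagen, by 1.86 (SE 0.25), *Postn* by 1.80 (SE 0.31), *Nox4* by 2.09 (SE 0.33) and *Cilp* by 2.20 (SE 0.44). *Ech1* fell by 0.80 (SE 0.11), from 14.69 (SD 0.23) to 13.89 (SD 0.13), and *Eci1*, another enzyme of fatty acid oxidation, by 0.88 (SE 0.13). *Nppa* was not called (-0.07, SE 0.27, adjusted p = 0.918), with means of 15.87 (SD 0.12) in sham and 15.80 (SD 0.08) in MI hearts. Its signals on these arrays, 52900 to 66782, are close to the highest signal of any probe set there (58410 to 84219), so a ceiling may hide a further rise. *Acta1*, skeletal alpha-actin, rose by 0.96 (SE 0.17). *Atp2a2*, the calcium pump SERCA2, fell by 0.31 (SE 0.08) and *Ppargc1a*, a coactivator of mitochondrial genes, by 0.64 (SE 0.19). On all of these arrays *Atp2a2* is brighter than the 99th percentile of signal. That percentile was 18260 to 20892 on dnPI3K sham and 16141 to 17234 on dnPI3K MI arrays. Part of the fall of *Atp2a2* may thus be a shift of bright signals.

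The count of genes called in dnPI3K hearts was 1390, 624 up and 766 down (limma, Benjamini-Hochberg). Other large increases were those of *Esm1* (2.22, SE 0.56), *Plcxd2* (2.10, SE 0.39), *Tspan32* (2.25), *Muc15* (2.20), *4930572G02Rik* (2.20) and *H2-Eb2* (2.05). The largest decreases were those of *Gnmt*, glycine N-methyltransferase (-2.59, SE 0.49), *1700071K01Rik* (-2.39), *Ano10* (-2.01, SE 0.25), *Retnla* (from 10.19 to 8.20), *Lgals4* (-1.86), *Mpo* (-1.81), *Wfdc15a* (-1.74), *Plet1* (-1.64), *Rnf225* (-1.60) and *Susd1* (-1.58). *Col1a1* (1.36, SE 0.34), *Col3a1* (1.34, SE 0.25) and *Timp1* (1.47, SE 0.29) rose and *Acadm* fell by 0.36 (SE 0.09), while *Nppb* (0.11), *Myh6* (-0.26), *Myh7* (0.73) and *Pln* (-0.24) did not pass, with adjusted p of 0.645, 0.06, 0.194 and 0.0666. The count was 844 without dnPI3K sham replicate 1 and 665 without the sham arrays numbered 415 to 418.

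Of the 57 matrix genes 40 rose in dnPI3K hearts and 0 fell (median 0.891, with 47 up and 1 down over the list alone), for example *Tgfb2* (1.43, SE 0.19) and *Fmod* (1.35). The adjusted p was 1.61e-37, and 0.0607 with an estimated correlation. Of 74 genes of oxidative phosphorylation 61 fell and 0 rose (71 down over the list alone, median -0.335), for example *Ndufs4* (-0.50, SE 0.08), *Ndufa6* (-0.51), *Cox8b* (-0.50) and *Atp5g2* (-0.54). For this list the adjusted p was 3.17e-41, and 0.111 with an estimated correlation, and the median was -0.10 after quantile normalization. Of 28 genes of fatty acid oxidation 18 fell (25 over the list alone, median -0.428), with *Decr1* at -0.74 and *Hsd17b10* at -0.60. Of 19 genes of the citric acid cycle 14 fell (17 over the list alone, median -0.318), with *Idh2* at -0.71 (SE 0.14), *Suclg2* at -0.54, *Suclg1* at -0.37 and *Idh3b* at -0.37. Their adjusted p of 8.56e-22 and 5.7e-14 were both 0.111 with an estimated correlation.

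Smaller shares of other lists moved after MI in dnPI3K hearts. In PPAR and PGC-1 regulated metabolism 6 of 20 genes fell, among them *Ppara* (-0.59, SE 0.14), *Pdk2* (-0.52), *Dgat2* (-0.71) and *Acot2* (-0.65). In calcium handling and ion channels 4 of 32 fell, among them *Kcnd2* (-0.66, SE 0.16), *Hrc* (-0.47) and *Trdn* (-0.39). Of 27 FoxO targets 5 fell (10 over the list alone), among them *Trim63*, a muscle ubiquitin ligase (-0.43, SE 0.11), *Sod2* (-0.34), *Ccng2* (-0.41) and *Bcl2l11* (-0.46). These lists shifted down at adjusted p of 0.00102, 0.000761 and 0.000592, and at 0.33, 0.318 and 0.0607 with an estimated correlation. Of 9 adipocyte markers 3 fell: *Adipoq* (-1.29, SE 0.32), *Car3* (-1.36, SE 0.39) and *Fabp4* (-0.24, or 0.01 after quantile normalization). They shifted down at 0.00485, and at 0.318 with an estimated correlation. Antioxidant and metallothionein genes went both ways: 3 of 27 rose, among them *Gpx3* (0.56), and 6 fell, among them *Gstk1* (-1.02, SE 0.14), *Prdx3* (-0.42) and *Gsta4* (-0.36). The list shifted down at 0.0108, and at 0.184 with an estimated correlation, and was not called after quantile normalization (0.331). Of 24 sarcomere genes 4 fell: *Tnni3* (-0.35), *Ckm* (-0.32), *Ckmt2* (-0.29) and *Pgam2* (-0.26). They shifted down at 5.14e-07, and at 0.369 with an estimated correlation, a shift whose direction was lost after quantile normalization (median 0, adjusted p = 0.981).

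Markers of other cells moved with the infarct in dnPI3K hearts as well. Of 20 fibroblast markers 9 rose (10 over the list alone), among them *Pi16* (1.67), *Islr* (0.90) and *Fbln2* (0.90). Of 26 macrophage markers 1 rose, *Laptm5* (0.79, SE 0.21). Of 12 mesothelial and epicardial markers 3 rose, *Krt18* (1.63), *Wt1* (0.80, SE 0.23) and *Sulf1* (0.69), and 1 fell, *Efemp1* (-0.81). These lists shifted up at adjusted p of 3.24e-09, 0.00978 and 0.0108, and at 0.111, 0.785 and 0.111 with an estimated correlation. Of 16 fetal and wall-stress genes 6 rose, among them *Synpo2l* (1.14, SE 0.14), *Rcan1* (1.35, SE 0.22) and *Fhl1* (0.93), and 1 fell. Their shift up had an adjusted p of 0.000144, and of 0.184 with an estimated correlation.

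In caPI3K hearts infarction also raised matrix genes. *Mfap4* rose by 4.69 (SE 0.71) from sham signals at background, a size that the pseudocount limits, *Col14a1* by 1.75 (SE 0.20), *Sfrp2* by 2.44 (SE 0.36), *Dio2* by 2.04 (SE 0.32) and *Postn* by 1.66 (SE 0.31). Both natriuretic peptides rose, *Nppa* by 1.32 (SE 0.27), from 14.01 (SD 0.48) to 15.34 (SD 0.16), and *Nppb* by 0.52 (SE 0.11). *Penk*, the precursor of enkephalins, fell by 1.85 (SE 0.32), *Efemp1*, a matrix protein, by 1.49 (SE 0.22), and *Pank1*, which makes coenzyme A, by 0.61 (SE 0.13). Of the 4 caPI3K sham arrays 3 carry Y-linked signal. Against the other array alone the changes are -0.754 for *Penk*, -0.855 for *Efemp1*, 2.02 for *Nppa* and 0.852 for *Nppb*. A single array has no spread of its own, so these values do not show what the arrays with Y-linked signal contribute. *Acta1* was not called (0.06, SE 0.17, adjusted p = 0.946).

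For caPI3K hearts limma with Benjamini-Hochberg adjustment called 164 genes, 126 up and 38 down. *Xist*, expressed from the inactive X chromosome, rose by 4.56 (SE 0.69), and *Uty*, a gene of the Y chromosome, fell by 2.62 (SE 0.66). These calls follow the sham arrays: 3 of the 4 caPI3K sham arrays have *Xist* at 6.77 to 7.08 and the Y-linked *Eif2s3y* at 10.55 to 10.99, while the other 21 arrays have *Xist* at 12.65 or above and *Eif2s3y* at 5.71 or below. Other increases were those of *Scg2* (2.87, SE 0.57), *Nbl1* (2.20), *Itih4* (2.01) and *Col8a2* (1.71, SE 0.32), and other decreases those of *Prr15l* (-2.67, at low signal), *Gm20559* (-0.74), *Amy1* (-0.73), *Katnal1* (-0.68), *2310040G24Rik* (-0.66) and *Asb12* (-0.61). Not called were *Col1a1* (0.96), *Col3a1* (0.96, adjusted p = 0.0596), *Timp1* (1.03, adjusted p = 0.0736), *Myh6* (-0.14), *Myh7* (0.20), *Atp2a2* (-0.07), *Pln* (-0.03), *Ppargc1a* (-0.18) and *Acadm* (-0.14). Without the 3 arrays with Y-linked signal, which leaves 1 caPI3K sham array, the count was 9. It was 101, 70 and 97 without caPI3K sham replicates 1, 2 and 4, 71, 96 and 89 without caPI3K MI replicates 1, 3 and 4, and 103 with a term for array numbers under 1000 and 405 in a fit on these groups alone.

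**Figure D1:**
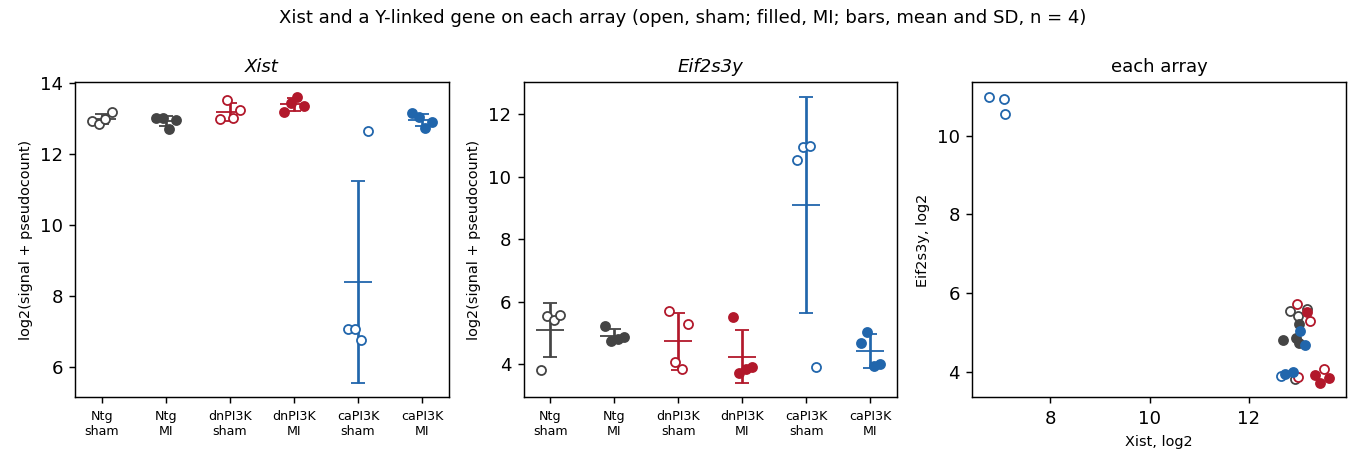
Log2 signal of *Xist* and *Eif2s3y* on each of the 24 arrays by group. The 3 caPI3K sham arrays with *Eif2s3y* at 10.55 to 10.99 are those with *Xist* at 6.77 to 7.08.

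Of 57 matrix genes 18 rose and 0 fell in caPI3K hearts (41 up over the list alone, median 0.619), for example *Fmod* (1.28) and *Comp* (1.43). Of 20 fibroblast markers 5 rose (17 over the list alone, median 0.493), for example *Pi16* (1.30), *Islr* (0.80) and *Tcf21* (0.51). Both lists, which share genes, passed camera, at adjusted p of 6.19e-39 and 4.57e-20, and at 0.0366 and 0.0355 with an estimated correlation. Macrophage markers (0 of 26 rose, 2 over the list alone, median 0.399), endothelial markers (median 0.146), immediate early genes (median 0.222) and interferon response genes (median 0.316) shifted up at 2.76e-08, 0.000468, 0.0382 and 0.000404. These were 0.25, 0.25, 0.644 and 0.53 with an estimated correlation. Relative to the mean over arrays, the interferon list was at -0.501, -0.314 and -0.324 on the caPI3K sham arrays with Y-linked signal. On caPI3K sham replicate 4, without such signal, it was at 0.303. The caPI3K MI arrays were at -0.106 to -0.007 for replicates 1 to 3 and at 0.560 for replicate 4. The interferon shift thus leans on the sham arrays with Y-linked signal and on MI replicate 4. Of 16 fetal and wall-stress genes 3 rose, among them *Ccn2* (1.01, SE 0.13), and 1 fell, *Mybpc2* (-0.50, SE 0.12). That list shifted up at 0.0258, and at 0.537 with an estimated correlation.

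Metabolic lists shifted down in caPI3K hearts with few single calls. Of 28 genes of fatty acid oxidation 0 passed and 18 fell over the list alone (median -0.277). Of 74 genes of oxidative phosphorylation 0 passed, also over the list alone (median -0.059), and of 19 genes of the citric acid cycle 4 fell over the list alone (median -0.178). Of 20 genes of PPAR and PGC-1 regulated metabolism 1 fell, *Ppargc1b* (-0.41, SE 0.10). These lists had adjusted p of 7.6e-15, 0.000158, 2.76e-08 and 1.43e-06 by camera, and 0.216, 0.644, 0.25 and 0.216 with an estimated correlation. Calcium handling (median -0.202), sarcomere genes (median -0.068), the circadian clock (median -0.174) and cardiac transcription factors (1 of 24 fell, *Gata6*, -0.48, SE 0.11) shifted down at 0.000129, 0.00848, 0.0395 and 0.0411. With the correlation estimated, they were at 0.25, 0.644, 0.25 and 0.216.

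Of the 35 tested lists, 10 were called in none of the 8 comparisons. They are glycolysis and glucose uptake (smallest adjusted p = 0.0538), the insulin, IGF1 and PI3K pathway (0.222), angiogenesis (0.132), ribosome biogenesis (0.207), renin-angiotensin, endothelin and adrenergic genes (0.184), and markers of smooth muscle and pericytes (0.147), skeletal muscle (0.398), lung epithelium (0.308), thymus (0.525) and Schwann cells and neurons (0.692), all by camera. Of 37 measured genes of the PI3K pathway list, 2, 4 and 3 rose and 0, 2 and 0 fell after MI in Ntg, dnPI3K and caPI3K hearts. Of 18 genes of glycolysis, 3 rose and 6 fell in dnPI3K hearts. Of 4 measured erythroid markers 0 were called after MI in any genotype, and of 3 measured genes of the Y-linked and *Xist* list 1 rose and 1 fell in caPI3K hearts.

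**Figure D2:**
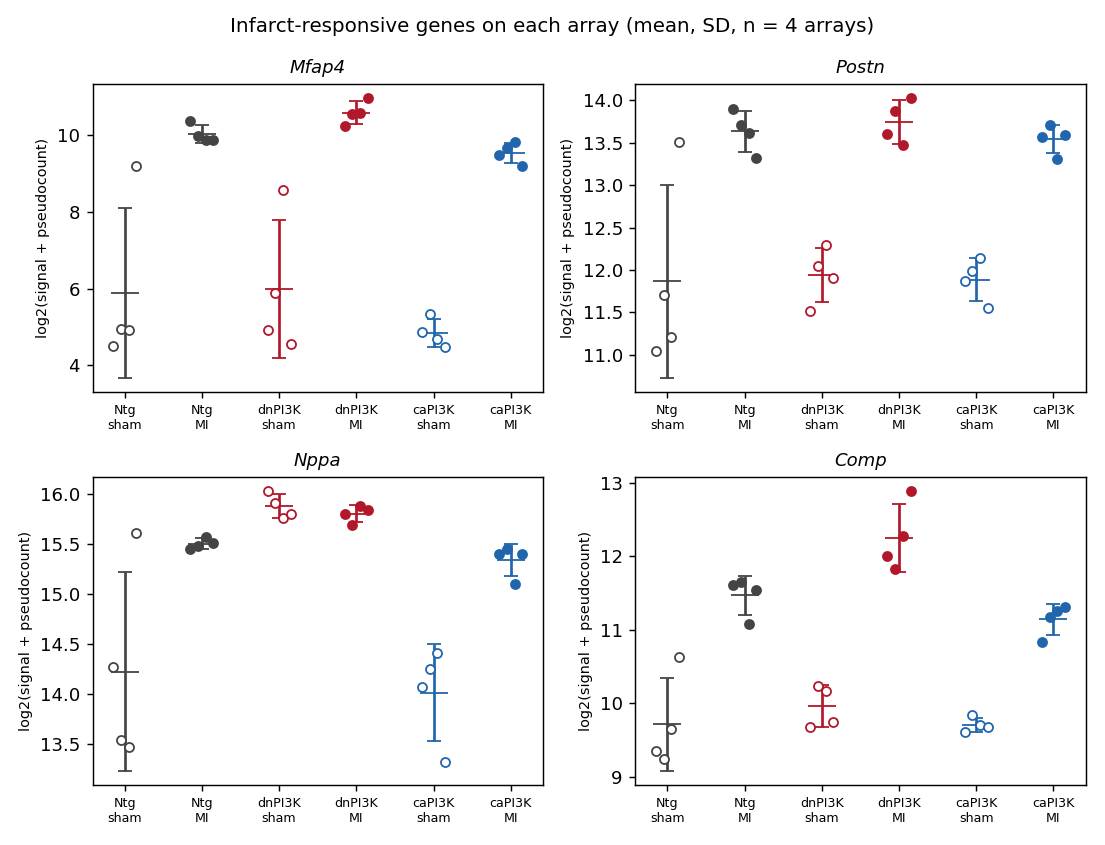
Log2 signal on each array for genes named in the comparisons of MI with sham, with group mean and SD (n = 4). *Mfap4* rises by 4.12, 4.59 and 4.69 and *Nppa* changes by 1.28, -0.07 and 1.32 in Ntg, dnPI3K and caPI3K hearts.

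Across genotypes, 48 genes rose after MI in all 3, and 0 fell in all 3. They include matrix and fibroblast genes such as *Comp* (1.75, 2.29 and 1.43 in Ntg, dnPI3K and caPI3K hearts), *Fmod* (1.28, 1.35 and 1.28), *Postn* (1.77, 1.80 and 1.66) and *Mfap4* (4.12, 4.59 and 4.69), and also *Nox4* (1.74, 2.09 and 1.29), *Dio2* and *Scg2* (2.61, 2.67 and 2.87). Genes called up in both Ntg and dnPI3K hearts numbered 84 (4.27 expected of independent lists), in Ntg and caPI3K 52 (0.862 expected) and in dnPI3K and caPI3K 86 (5.33 expected), with Fisher p of 5.95e-100, 1.89e-84 and 5.17e-89 that treat genes as independent. Called down in both were 10 (0.726 expected), 0 (0.036 expected) and 17 (1.97 expected). On leaving out 1 array, genes called in the same direction in both ranged over 22 to 491, 19 to 146 and 49 to 110. The 48 genes were not recounted in this way. The MI effects correlated over all genes at 0.242, 0.185 and 0.208 and had the same sign for 62.3%, 58.4% and 58.9% of all genes. Of the 115 genes called in Ntg hearts 109 moved in the same direction in dnPI3K (median size 0.741 against 0.827 in Ntg) and 108 in caPI3K hearts (median 0.620). Of the 1390 called in dnPI3K hearts 1293 (93.0%) had the same direction in Ntg and 1162 (83.6%) in caPI3K hearts, at median sizes of 0.213 and 0.157 against 0.483 in dnPI3K, where selection by size favours dnPI3K. In Ntg hearts these are 1307 (94.0%) and 0.282 without Ntg sham replicate 4, and 1105 (79.5%) and 0.115 without the sham arrays numbered 415 to 418, which leaves replicates 3 and 4 as the Ntg sham arrays. The order of Ntg and caPI3K hearts thus depends on which sham arrays are used.

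**Figure D3:**
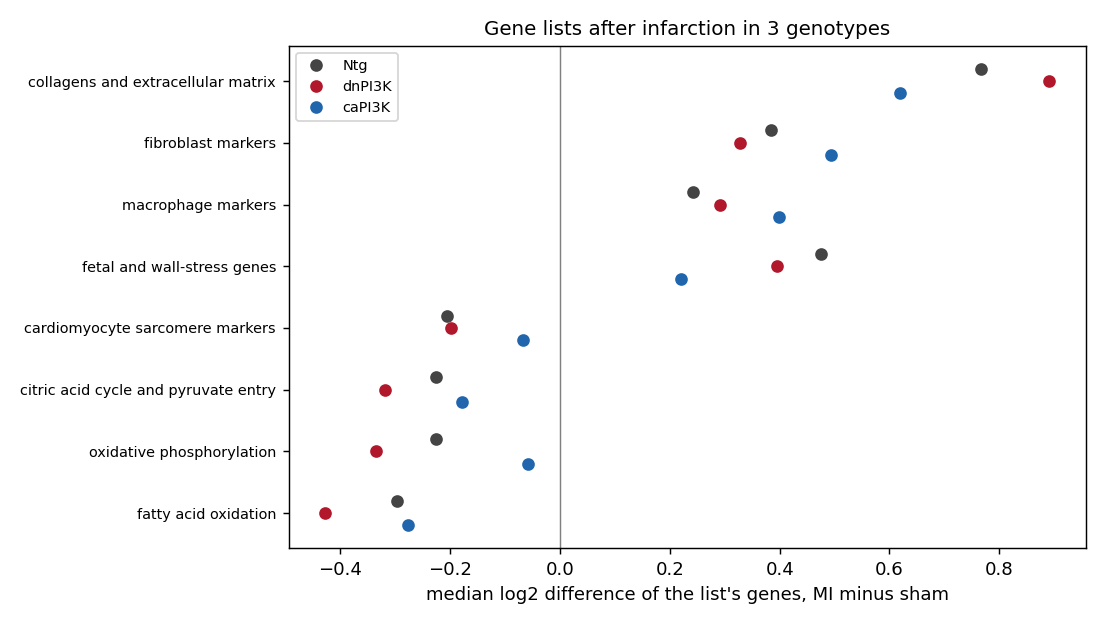
Median log2 change after MI of the genes of each list, by genotype. Matrix genes are at 0.767, 0.891 and 0.619 and genes of oxidative phosphorylation at -0.225, -0.335 and -0.059 in Ntg, dnPI3K and caPI3K hearts.

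Direct tests of a difference between genotypes in the MI effect called 0 genes in each of the 3 contrasts (limma, Benjamini-Hochberg). *Nppa* changed by 1.35 less in dnPI3K than in Ntg hearts (-1.35, SE 0.39, adjusted p = 0.504) and by 1.39 more in caPI3K than in dnPI3K hearts (SE 0.39, adjusted p = 0.181), with dnPI3K signals near the top of the array's range. *Acta1* differed by -0.90 between caPI3K and dnPI3K hearts (SE 0.24, adjusted p = 0.179), and *Postn* by 0.03 between dnPI3K and Ntg (SE 0.43, adjusted p = 0.992). So in the fit over all 24 arrays the larger count in dnPI3K hearts is not shown to be a different response of any gene, but a fit on the compared groups alone calls 63 genes between caPI3K and dnPI3K. Without Ntg sham replicate 4, *Nppa* is the only gene called between dnPI3K and Ntg (-1.81, adjusted p = 0.000883), and without Ntg sham replicate 2 *Cox16* is the only such gene. Between caPI3K and Ntg, 2 genes are called without caPI3K sham replicate 4 (*Eif2s3x* and *Xist*), and between caPI3K and dnPI3K 4 are called without dnPI3K MI replicate 1 (*Adipoq*, 2.56, *Car3*, 2.43, *Ggct* and *Gnmt*). For the latter contrast 3 are called without caPI3K sham replicate 4 (*Eif2s3x*, *Ppip5k1* and *Xist*) and 1, *Naa38*, without dnPI3K sham replicate 2 or dnPI3K MI replicate 4. Without the sham arrays numbered 415 to 418, 2 genes are called between dnPI3K and Ntg and 1 between caPI3K and Ntg, and without the arrays with Y-linked signal 1 between caPI3K and Ntg.

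Unadjusted p was below 0.05 for 1122 genes between dnPI3K and Ntg, 815 between caPI3K and Ntg and 1503 between caPI3K and dnPI3K, with smallest adjusted p of 0.243, 0.464 and 0.0732. The genes of smallest p, given as values only, were *Cox16* (-0.75, SE 0.14), *Myl7* (-2.75, SE 0.58), *Pdcd2* (-0.81), *Mfap3* (0.58) and *Htra4* (1.10) for dnPI3K against Ntg. For caPI3K against Ntg they were *Aen* (-0.63, SE 0.13), *Xist* (4.61, SE 0.97), *Pms2* (-2.12), *4930448K20Rik* (2.54) and *Myl7* (-2.49, SE 0.58). For caPI3K against dnPI3K they were *Naa38* (0.55, SE 0.10), *Ggct* (0.78, SE 0.15), *Kif5c* (-2.20, SE 0.44), *Gnmt* (3.43, SE 0.69) and *Plet1* (3.59, SE 0.72). Lists were called by camera in 7, 6 and 11 cases, and in 0 with an estimated correlation, whose smallest adjusted p were 0.365, 0.171 and 0.182. For oxidative phosphorylation the median difference was -0.126 between dnPI3K and Ntg and 0.262 between caPI3K and dnPI3K (19 of 74 higher over the list alone, adjusted p = 1.3e-28, and 0.316 with an estimated correlation). The latter median was 0.048 after quantile normalization.

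Among sham hearts, some single genes of muscle differed between dnPI3K and Ntg hearts, but sarcomere genes (1 of 24 lower, adjusted p = 0.0871 by camera) and skeletal muscle markers (1 of 9 lower, 5 positive and 4 negative changes, adjusted p = 0.398) were not called as lists. *Nppa* was higher by 1.65 (SE 0.27), with means of 15.87 (SD 0.12) and 14.22 (SD 0.99, n = 4 each). The dnPI3K signals may be at a ceiling, so no fold is given. Ntg sham replicate 4 is at 15.61 and the other Ntg sham arrays at 13.47 to 14.27. The difference is 2.12 without that array. It is 1.24 and not called (adjusted p = 0.304) without the sham arrays numbered 415 to 418, which leaves Ntg sham replicates 3 and 4, so this smaller value rests on replicate 4. *Myl1*, a myosin light chain, was lower by 2.12 (-2.12, SE 0.20), *Casq1*, the skeletal form of calsequestrin, by 1.52 (-1.52, SE 0.17), and *Scn4b*, a sodium channel beta subunit, by 1.06 (-1.06, SE 0.19). *Bex1* was higher by 2.94 (SE 0.39), or by 2.28 without Ntg sham replicate 4, which is at 8.60 where the other Ntg sham arrays are at 10.98 to 11.42. *Dusp4*, a MAP kinase phosphatase, was higher by 1.95 (SE 0.25). Enzymes that carry or handle fatty acids for oxidation were lower, *Slc25a20* (-0.49, SE 0.09) and *Cpt2* (-0.48, SE 0.12). *Cpt2* is not called when any one of Ntg sham replicates 1 to 3 or dnPI3K sham replicates 1 to 3 is left out.

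Limma with Benjamini-Hochberg adjustment called 165 genes here, 61 higher and 104 lower in dnPI3K sham hearts. Others with large differences were *Colq* (2.38), *Tceal7* (2.13, SE 0.40), *Tmem100* (1.75, SE 0.23), *Slc38a1* (1.58, SE 0.22), *Gbp6*, *Gnb3* (1.35, SE 0.22) and *Upp1* (1.19). Lower were *Cyp2b10* (-2.99, SE 0.39), *Lgi1* (-2.73, SE 0.42), *Igsf1* (-2.16, SE 0.32), *Il3ra* (-2.04), *0610025J13Rik* (-1.89), *Sh3gl2* (-1.76), *Gm10336* (-1.46) and *Pla2g5* (-1.44, SE 0.35). *Nppb* (0.40, adjusted p = 0.102), *Postn* (0.07), *Acta1* (-0.32) and *Ppargc1a* (0.46) did not pass. Fatty acid oxidation (2 of 28 lower, median -0.192), calcium handling and ion channels (2 of 32 lower, median -0.072) and heat shock genes (0 of 27, median -0.155) shifted down by camera, at adjusted p of 3.16e-06, 0.00377 and 0.000461. Immediate early genes (median 0.370), chemokines, cytokines and complement (median 0.339), interferon response (median 0.306) and MHC genes (median 0.348) shifted up, at 0.0019, 0.00232, 0.00377 and 0.0358. None of the 7 lists was below 0.747 with an estimated correlation. The interferon and MHC shifts lean on dnPI3K sham replicate 1, with list medians of 0.410 and 0.869 relative to the mean over arrays. The other dnPI3K sham arrays were at -0.164 to 0.042 and -0.108 to 0.061. Without Ntg sham replicate 4, *Colq*, *Gbp6*, *Il3ra*, *0610025J13Rik* and *Pla2g5* do not pass. The count of genes was 77 without dnPI3K sham replicate 2, 38 without the arrays numbered 415 to 418 and 73 in a fit on these groups alone.

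Between caPI3K and Ntg sham hearts the called genes go both ways. *Scn4b* was higher by 0.94 (SE 0.19), *Mybpc2*, a myosin-binding protein, by 0.67 (SE 0.12) and *Rras2* by 0.46 (SE 0.08). *Pde1c*, a cyclic nucleotide phosphodiesterase, was lower (-1.30, SE 0.19), as were *Tfpi*, an inhibitor of coagulation (-0.87, SE 0.14), *Gsta3* (-1.58, SE 0.29), *Il33* (-0.95, SE 0.18), *Col14a1* (-1.01, SE 0.20) and *Myom2* (-0.71, SE 0.13). *Nppa* (-0.21, adjusted p = 0.853) and *Acta1* (0.63, adjusted p = 0.121) did not pass. Without Ntg sham replicate 4, *Acta1* passes (0.92, adjusted p = 3.82e-05) and *Nppa*, still not called, turns to 0.26.

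The 38 genes called (limma, Benjamini-Hochberg; 16 higher, 22 lower) also include *Cep19* (0.72), *Ino80c* (0.65), *Dhx32* (0.58), *Lrtm1* (0.55), *Pex19* (0.44), *Aen* (0.42), *Mvb12a* (0.41), *Ifitm1* (-1.21, SE 0.24), *Acbd4* (-0.89), *Slc7a1* (-0.79) and *Mturn* (-0.76), and *Xist* (-4.59, SE 0.69), which follows the 3 arrays with Y-linked signal. Oxidative phosphorylation (median -0.172), the citric acid cycle (median -0.094) and sarcomere genes (median -0.164) shifted down at adjusted p of 2.03e-22, 0.0223 and 4.27e-07, but at 0.659, 0.692 and 0.659 with an estimated correlation, and after quantile normalization their medians were 0.007, 0.036 and 0.022. Endothelial (median -0.082) and adipocyte markers (median -0.212) shifted down and atrial markers up (median 0.384), at 0.0371, 0.0145 and 0.00247, and at 0.659 each with an estimated correlation. The endothelial and adipocyte lists were not called after quantile normalization (0.0596 and 0.0924). The count was 12, 13, 23 and 411 without Ntg sham replicates 1 to 4, 19, 10, 16 and 21 without caPI3K sham replicates 1 to 4, and also moved to 4 without the 3 arrays with Y-linked signal, and 5 without those numbered 415 to 418. It was 15 with a term for array numbers under 1000, 5 in a fit on these groups alone and 67 over all probe sets. Whether dnPI3K or caPI3K sham hearts differ from Ntg in more genes is not settled, as the counts are 165 and 38 with all arrays and 166 and 411 without Ntg sham replicate 4. Other groupings of these 8 arrays call up to 90.

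Both transgenic sham groups were compared with the same Ntg sham arrays, and 11 genes were called in both, all in opposite directions. They are *Igsf1* (-2.16 in dnPI3K, 1.46 in caPI3K), *Scn4b* (-1.06 and 0.94), *Lrtm1* (lower in dnPI3K, 0.55 in caPI3K), *Mybpc2* (-0.72 and 0.67), *Clu* (-0.89 and 0.41), *Mtus1* (-0.33 and 0.38), *Pde1c* (0.91 and -1.30), *Tfpi* (0.63 and -0.87), *Pygl* (0.58 and -0.63), *Atpif1* (0.68 and -0.53) and *Ehd4* (0.38 and -0.53). Independent lists would share 0.204 genes in opposite directions. Shared controls push effects the same way, to a correlation of 0.467 in simulated unchanged groups, and the observed correlation was 0.304. With the Ntg sham arrays split so that the comparisons share no array, 21.2 genes on average (0 to 62 over 6 ways) were called in opposite directions and 0 in the same direction.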

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

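Tests chosen only after the result was seen are those of a swap, of atrial tissue and of a caPI3K origin for Ntg sham replicate 4, those of sex as the source of the *Xist* and Y-linked calls and of the called rises, those on the sham arrays numbered 415 to 418, and the regroupings for caPI3K against dnPI3K hearts over both operations. Regroupings for the 8 comparisons, the test for an infarct under the sham label and the score for sex as the whole source of the caPI3K response were set before their results were seen.

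Ntg sham replicate 4 stood apart from the other Ntg sham arrays, by Dixon's test, in the median of matrix genes (0.225 against -0.728 to -0.590), the median of fibroblast markers (0.201 against -0.418 to -0.391) and *Acta1* (15.32 against 14.15 to 14.17). On 103 genes that mark infarction in dnPI3K and caPI3K hearts its score was 0.834, with the other Ntg sham arrays at -0.022 to 0.017 and Ntg MI at 0.987 to 1.186 (SD 0.093), so a swap with an Ntg MI array is argued against by the lowest MI score of 0.987, an infarct of the usual extent in an Ntg heart by the 0.834, and atrial tissue by the matrix medians of other sham hearts with as much *Myl7*, at most -0.154. Genes that separate caPI3K from dnPI3K arrays place it elsewhere: on 298 such genes, chosen without Ntg arrays, it scored 0.856, within the caPI3K range (0.793 to 1.149) and above the other 7 Ntg arrays (0.556 to 0.712). Against the caPI3K sham mean its infarct score on 1348 genes was 0.326, within the 0.307 to 0.456 of the caPI3K MI arrays. No other Ntg array was scored in this way, so that score does not tell caPI3K from Ntg. With genes centred over the arrays, it correlated at 0.001 with caPI3K MI, -0.003 with caPI3K sham and -0.019 with Ntg MI means. These do not decide, as Ntg MI replicate 3 was also nearest to caPI3K MI. By the genotype score, an infarcted caPI3K heart under an Ntg sham label is possible. An Ntg heart with a smaller infarct or other injury and a shifted genotype score stays open, and genotyping or transgene-specific reads of that RNA would decide.

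The response in caPI3K hearts rests on sham arrays that differ in sex-linked genes, and *Xist* of caPI3K sham replicate 4 (12.65 against 6.77 to 7.08) and its *Eif2s3y* (3.90 against 10.55 to 10.99) stood apart. The gap of 5.56 log2 units in *Xist* is what a female heart among 3 male hearts would give, and sex is the likely source of the *Xist* and Y-linked calls. Sex as the whole source of the response is argued against by its overlap with Ntg and dnPI3K hearts, whose arrays all have *Xist* at 12.65 or above and *Eif2s3y* at 5.71 or below: of the 126 genes that rose, 86 were also called up in dnPI3K hearts (5.33 expected of independent lists) and 52 in Ntg hearts (0.862 expected), and 157 of all 164 moved in the same direction in dnPI3K hearts. On 1348 genes the caPI3K MI arrays scored 0.432 (SD 0.062) against the sham array without Y-linked signal and 0.374 against the 3 with it, where Ntg MI arrays scored 0.598. That score does not decide, since it lies between the bounds of 0.2 and 0.5 set in advance and rests on 1 sham array. Sex as the source of part of the calls stays open. The 4 caPI3K sham arrays are also numbered 1410 to 1417, and all other arrays 1191 or below. What these numbers stand for is not given, and the term for numbers under 1000 does not adjust for this block. Anything that goes with it cannot be told apart from the caPI3K sham group.

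Genes of oxidative phosphorylation moved down after MI while the sham arrays numbered 415 to 418 carried higher values for them (median 0.219 above the other Ntg and dnPI3K sham arrays, exact permutation p = 0.0556, the smallest possible with 36 arrangements). Ribosomal protein genes were higher there by 0.218 and the log2 99th percentile of signal by 0.161 (exact permutation p = 0.0556 each). The shift is thus not particular to mitochondria, and the equal trimmed means of the arrays do not remove it. Without these arrays the median change in Ntg hearts was -0.069 instead of -0.225 (-0.089 to -0.050 on leaving out a further array), which does not decide whether these arrays are the whole source. In dnPI3K hearts it stayed at -0.276 (all arrays -0.335), which argues against them as the whole source there. Ribosomal protein genes moved down after MI too, with a median of 45 genes of -0.161 in Ntg hearts (-0.019 without these arrays). In dnPI3K hearts that median was -0.248 (-0.164 without these arrays), and the oxidative phosphorylation list was at -0.10 after quantile normalization. A shift that is not particular to mitochondria thus stays open as the source of part of the fall.

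For MI in Ntg hearts, 4 of 35 groupings of the 8 arrays called at least the real 115 genes, the highest other being 356, so this count does not exclude chance. The genes do argue against chance as the whole source, since 84 of the 101 that rose were also called up on the separate arrays of dnPI3K hearts (4.27 expected) and 52 on those of caPI3K hearts (0.862 expected). The grouping with 356 exchanges Ntg sham replicate 4 and Ntg MI replicate 3, which points to a structure of the samples, that of the sham array described above. Chance is argued against for MI in dnPI3K hearts (1 of 35, real 1390, highest other 4). So it is for MI in caPI3K hearts (1 of 35, real 164, highest other 3) and dnPI3K against Ntg sham (1 of 35, real 165, highest other 19). The 1 is the real grouping itself, the smallest share that 35 groupings can give, so chance is not excluded. Regrouping also cannot tell operation or genotype from anything else that differs between the groups, such as sex-linked signal. For caPI3K against Ntg sham the count leaves chance open (2 of 35, real 38, highest other 90). For the differences of MI effects the real count is 0, which every grouping reaches by construction (100 of 100), so regrouping says nothing of chance there. The highest counts were 83 for dnPI3K against Ntg, 5 for caPI3K against Ntg and 1930 for caPI3K against dnPI3K. The last exchanges all dnPI3K MI arrays with all caPI3K MI arrays and so counts the genotype difference itself, a structure of the samples. For that difference over both operations 1 of 100 groupings, the real one, reached 1930 (highest other 894), which argues against chance.

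Numbers of lists called by camera do not exclude chance in any comparison. For MI in Ntg, dnPI3K and caPI3K hearts, 10, 2 and 5 of 35 groupings called at least the real 14, 14 and 15 lists (highest others 17, 14 and 18). For the sham comparisons 26 and 27 of 35 groupings reached the real 7 and 6 (highest others 15 and 14). For the differences of MI effects 58, 63 and 15 of 100 reached the real 7, 6 and 11 (highest others 18, 18 and 20), and for genotype over both operations 59 of 100 reached 6 (highest other 16).

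Lists whose MI effect was called different between genotypes by camera were singled out for that reason, and none of these calls holds with an estimated correlation. Between dnPI3K and Ntg the medians were 0.214 for matrix genes, -0.150 for fatty acid oxidation, -0.126 for oxidative phosphorylation, -0.099 for the citric acid cycle, -0.643 for atrial markers, -0.118 for FoxO targets and -0.503 for MHC genes, at adjusted p of 0.00293, 0.00153, 2.24e-07, 0.00751, 0.00293, 0.00794 and 0.0213 (0.365 or above with an estimated correlation). After quantile normalization the citric acid cycle was at -0.024 and not called (0.384), FoxO targets were not called (0.0919) and oxidative phosphorylation was at -0.063. Between caPI3K and Ntg they were 0.156 for oxidative phosphorylation, 0.094 for sarcomere genes, 0.423 for lymphocyte markers, 0.224 for endothelial markers, 0.262 for adipocyte markers and -0.271 for atrial markers (0.171 or above); after quantile normalization oxidative phosphorylation was at 0, sarcomere genes at -0.059 and adipocyte markers at 0.249, none of them called. Between caPI3K and dnPI3K they were -0.413 for fetal and wall-stress genes, -0.336 for matrix genes, 0.192 for fatty acid oxidation, 0.262 for oxidative phosphorylation, 0.177 for the citric acid cycle, 0.129 for sarcomere genes, 0.506 for adipocyte markers, -0.765 for mesothelial and epicardial markers, 0.175 for FoxO targets, 0.181 for antioxidant genes and 0.536 for MHC genes (0.182 or above); after quantile normalization fatty acid oxidation was at 0.022, the citric acid cycle at -0.036, sarcomere genes at -0.030, antioxidant genes at 0.092, FoxO targets at 0.136 and MHC genes at 0.550, none of them called, and oxidative phosphorylation was at 0.048. The MHC call was also lost at a pseudocount of 1.12 (0.0511). MHC medians lean on single arrays, with Ntg MI replicate 1 at 1.246 (others of its group -0.381 to -0.220). Likewise caPI3K MI replicate 4 was at 1.197 (others -0.255 to -0.008) and dnPI3K sham replicate 1 at 0.869 (others -0.108 to 0.061).

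Dixon's test singled out 19 of 174 sets of 4 arrays, where 8.7 are expected by chance at 1 in 20. Besides those above they are *Pik3ca* in Ntg sham replicate 2 (10.01 against 10.69 to 10.79) and caPI3K sham replicate 1 (10.70 against 10.55 to 10.57), *Nppa* in caPI3K MI replicate 3 (15.10 against 15.40 to 15.45), *Timp1* in dnPI3K MI replicate 4 (10.03 against 9.15 to 9.29), *Pln* in caPI3K sham replicate 1 (15.75 against 15.65), *Ppargc1a* in caPI3K MI replicate 2 (10.87 against 10.37 to 10.43) and *Acadm* in Ntg MI replicate 1 (14.81 against 14.97 to 15.00). *Eif2s3y*, at background on these arrays, stood apart in Ntg sham replicate 1 (3.81 against 5.42 to 5.59) and dnPI3K MI replicate 1 (5.51 against 3.71 to 3.91). Further values were the median of oxidative phosphorylation in dnPI3K sham replicate 1 (0.342 against 0.064 to 0.108), the median of atrial markers in Ntg MI replicate 3 (0.031 against 0.321 to 0.380) and the 18S control in Ntg sham replicate 1 (12.25 against 10.10 to 10.28). dnPI3K MI replicate 1 had a median signal of 150.7 (others 109.2 to 115.2) and a mean correlation with other arrays of 0.918 (others 0.950 to 0.951).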

How the results depend on the processing

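Counts of called genes depend on the processing and on single arrays, and for those that moved the cause was not tested. Of the counts under alternatives other than leaving out 1 array, 21 moved by more than 1.5-fold or from 0, and 76 did not. For MI in Ntg hearts (115) the count was 10 in a fit on the compared groups and 9 without the sham arrays numbered 415 to 418; for dnPI3K (1390) it was 665 without these; for caPI3K (164) it was 103 with a term for array numbers under 1000, 405 on the compared groups and 9 without the 3 arrays with Y-linked signal. Differences of MI effects (0 called) gave 2 genes for dnPI3K against Ntg without arrays 415 to 418 (*Cox16*, *Trav9d-3*), 1 for caPI3K against Ntg without these (*Trav9d-3*) and 1 without the Y-linked arrays (*Myof*), and for caPI3K against dnPI3K 1 over all probe sets and 63 on the compared groups. dnPI3K against Ntg sham (165) gave 73 on the compared groups and 38 without arrays 415 to 418; caPI3K against Ntg sham (38) gave 67 over all probe sets, 15 with the array-number term, 5 on the compared groups, 4 without the Y-linked arrays and 5 without arrays 415 to 418. Calls of lists went from 80 to 3 with an estimated correlation, genes opposite in the sham comparisons from 11 to 21.2 with split controls, and genes differing between caPI3K and dnPI3K over both operations from 1930 to 894 without the Y-linked arrays. Leaving out 1 array gave 25 to 674 (Ntg MI), 844 to 1333 (dnPI3K MI), 70 to 168 (caPI3K MI), 0 to 1, 0 to 2 and 0 to 4 (differences of MI effects), 77 to 187 and 10 to 411 (sham), 1648 to 1885 (genotype) and 72 to 91 lists; shared MI genes ranged over 22 to 491, 19 to 146 and 49 to 110. Under alternatives other than leaving out 1 array 184 values of named genes lost their call, 17 gained it, 199 of uncalled genes moved by more than their SD, 2391 did none of these and 1 reversed (*Fabp4* after MI in dnPI3K hearts, 0.01 after quantile normalization). On leaving out 1 array 381 values lost their call, 65 gained it, 15 of uncalled genes moved by more than their SD and 4953 did none of these. Leaving out the 3 arrays with Y-linked signal leaves 1 caPI3K sham array, whose spread is then taken from the other groups, and leaving out arrays 415 to 418 leaves Ntg sham replicates 3 and 4. No paired analysis was possible because the array numbers are not shared between groups. Signal near background limits the fold changes of dim genes.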

Other observations

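Tests of genotype over both operations and the genotype score were chosen only after the result was seen. The test of *Nppa* between genotypes and the leaving out of each array in turn were planned. Exclusions of arrays by Y-linked signal or by array number were added after the data were examined. Over sham and MI together, caPI3K hearts differed from dnPI3K hearts in 1930 genes (1104 higher, 826 lower; limma, Benjamini-Hochberg), and the genes named here were chosen after values were seen. *Lrtm1* and *Clu* are from the 11 genes opposite in the sham comparisons, and the others are some of the 10 genes with the largest difference in each direction and no overlap of arrays. *Myl1* was higher in caPI3K hearts by 2.48 (SE 0.14), with means of 14.92 (SD 0.12) in caPI3K, 14.20 (SD 0.42) in Ntg and 12.44 (SD 0.47) in dnPI3K hearts (n = 8 each). *Scn4b* was higher by 1.90 (SE 0.14), *Igsf1* by 2.63 (SE 0.23), *Lgi1* by 2.81 (SE 0.30), *Lrtm1* by 1.54 (SE 0.08) and *Clu*, clusterin, by 1.08 (SE 0.06). *Bex1* was lower (-4.02, SE 0.28, 16.3-fold), with means of 9.15 (SD 0.48), 10.78 (SD 0.91) and 13.17 (SD 0.58) in the same order, as were *Dusp4* (-2.29, SE 0.18), *Pde1c* (-1.83, SE 0.14), *Tceal7* (-2.59), *Tmem100* (-2.23) and *Gnb3* (-1.66). For 307 genes no caPI3K array overlaps a dnPI3K array, which chance gives for 0.0155% of genes. The Ntg mean lies between the transgenic means for 306 of these and for 90.1% of the called genes, against 45.7% of all tested genes, a share that selecting large differences raises in part.

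Fatty acid oxidation (15 of 28 higher in caPI3K, 1 lower; median 0.218), calcium handling and ion channels (11 of 32 higher, 1 lower; median 0.244) and heat shock genes (10 of 27 higher, 0 lower; median 0.157) shifted up by camera at adjusted p of 2.18e-07, 5.12e-05 and 3.85e-05, and at 0.76, 0.509 and 0.509 with an estimated correlation. Fibroblast markers (4 of 20 lower, 1 higher; median -0.166), endothelial markers (4 of 21 lower; median -0.105) and immediate early genes (2 of 23 lower; median -0.197) shifted down at 0.00982, 0.00982 and 0.0347, and at 0.76 each with an estimated correlation.

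A hypothesis is that the level of PI3K activity sets the expression of some of these genes. None of the other drawn groupings of the arrays reached 1930, which bears on chance and not on the hypothesis itself. Independence of the operation is not shown, as the genotype score of the caPI3K MI arrays (0.793 to 0.882) lies below that of the caPI3K sham arrays (1.008 to 1.149). Sarcomere genes as a list were not called (adjusted p = 0.406). The count dropped to 894 without the 3 caPI3K sham arrays with Y-linked signal and was 1387 without arrays 415 to 418. A sex difference and the separate breeding of the lines stay among the possible explanations for part of the 1930, and the insertion site of a transgene may add genes of its own. A line with an inducible transgene, measured in animals of known sex, would separate these.

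A further hypothesis is that reduced PI3K activity leaves *Nppa* at an infarct-like level before any infarct. Its value in dnPI3K sham hearts was 15.87 (SD 0.12), above the 15.50 (SD 0.05) of Ntg MI hearts. Signals at this level are close to the highest on these arrays, so a ceiling may hide a rise after MI. Other atrial markers also had lower MI effects in dnPI3K than in Ntg hearts (*Myl7* by -2.75, SE 0.58, adjusted p = 0.352 by limma, median of 13 atrial markers -0.643). A difference in atrial tissue between samples thus stays open for the MI effect. In caPI3K hearts *Myl7* differed similarly (-2.49, SE 0.58) while *Nppa* rose by 1.32, as in Ntg hearts (1.28, difference 0.04, SE 0.39). Both *Myl7* differences are taken against the same Ntg arrays, so their likeness does not decide. Atrial list medians relative to the mean over arrays were 0.244 to 0.628 on caPI3K sham and -0.407 to 0.330 on dnPI3K sham arrays. *Nppa* was at 13.32 to 14.41 on the former and 15.76 to 16.03 on the latter. These values argue against atrial tissue as the whole source of the higher sham level. The higher sham level is not called without the sham arrays numbered 415 to 418 (1.24, adjusted p = 0.304), where replicate 4 is 1 of the 2 Ntg sham arrays left, and is 2.12 without replicate 4. Its MI effect was called different from that in Ntg hearts only when Ntg sham replicate 4 was left out, the array whose genotype score of 0.856 suggests a caPI3K origin. More Ntg sham hearts would test it.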
